A study of Mus musculus with 24 samples.

How the data were processed

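RNA-seq was analysed from 24 libraries of EMS404 mouse hepatic stellate cells in 8 groups, with biological samples in triplicate per the labels' design statement. The library names give DMSO vehicle for the group that the labels call untreated, and it is called vehicle here. RNA came from either of 2 purification kits depending on yield, per the labels' protocols, and which samples had which kit is not given in the sources used here. Reads were aligned to mm10 with HISAT2 2.0.4 and Bowtie2 2.2.5, levels were estimated with RSEM and groups were compared with DESeq2, per the submitters' processing notes. The deposited table holds FPKM with 2 decimals for 16620 lines in 24 columns, all of which were mapped to a sample by name. It holds 16612 gene identifiers, of which 8 stood on 2 lines each, and these 16 lines were left out because the lines could not be told from each other. The remaining 16604 genes were used, with symbols and GRCm38 positions from GENCODE M21 for matched identifiers, 43 of 16612 having no match. No mitochondrially encoded gene was in the table. 57 genes were 0 in all libraries.

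Read counts and depth per library are unknown. FPKM summed to 504304 to 610449 per library, and the relative depth, taken from the smallest value steps of 54 genes with zeros in at least 8 libraries, ranged from 0.94 to 1.08. Genes with FPKM of at least 1 in at least 3 of the 24 libraries (11297 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with trend and robust variance moderation and all 8 groups in 1 model (16 residual degrees of freedom, median 22.6 after moderation). P values were 2-sided and adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The 13 comparisons were TGFb and each compound against vehicle, each compound with TGFb against TGFb and against the same compound alone, and the interaction of each compound with TGFb. The median standard error was 0.064 for a log2 fold change between groups and 0.09 for an interaction. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

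Comparisons, alternatives and 31 gene lists were fixed before the data were examined. The 26 lists with at least 4 tested members were tested with camera from limma at a correlation of 0.01 between genes, and again with an estimated correlation and with fry, each adjusted over the 26 lists of a comparison. Those lists cover the clock (core clock, CLOCK:BMAL1 E-box targets, REV-ERB and ROR element targets), TGFb-SMAD and BMP-SMAD responses, collagens, other matrix proteins, matrix crosslinking and turnover, contractile and quiescent stellate cell genes, portal fibroblast and mesothelial markers, proliferation, inflammation, interferon, YAP-TEAD, immediate early, p53, NRF2 and AhR targets, the integrated stress response, ER chaperones, autophagy and lysosome, glycolysis, oxidative phosphorylation, cholesterol synthesis and fatty acid synthesis. Named genes were fixed by rule, beginning with the 8 largest called rises and falls for TGFb against vehicle and for each compound without and with TGFb. In these, the 3 libraries of one group all had to lie on the same side of the other 3. The 5 largest called interactions in each direction were named without that condition. Up to 4 list members with the smallest adjusted p were added, and 19 genes were named in every case, such as Acta2, Col1a1 and Arntl. Genes with clone or predicted names were counted but not named, and a few genes that the rule names are not reported. The slope of the TGFb response with a compound was fitted over genes that TGFb alone changed at least 2-fold, with its SD over the 3 libraries with compound and TGFb. Overlap of gene lists was compared with the number for independent lists, and 100 simulations of unchanged groups gave the correlation and covariance that shared controls cause where no gene changes. Exchanges of library labels between groups counted how often other splits gave as many called genes.

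Alternatives were pseudocounts of 0.1 and 0.5, no filter or FPKM of at least 5, TPM, quantile normalization, variance moderation without trend, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. For the gene list tests, SR9011 replicate 1 was the only library left out. The labels do not say that a replicate number marks a shared batch or day, so pairing was judged from the residual correlations of samples with the same number. They were over 0.1 in all 3 pairs for 2 of 28 pairs of groups, namely SB431542 with SB431542+TGFb (0.415, 0.208 and 0.117) and SB431542+TGFb with CLK8+TGFb, which were not compared. By this rule, TGFb within SB431542 alone counted as paired among the groups compared, though the rule cannot exclude pairing elsewhere. The main fit left this pairing out. The block was shared by all groups, so the pairing alone was not fitted. The fit was tested on simulated data with vehicle means, independent libraries and 1 fitted spread per gene for all groups. For the recovery of genes, 200 of 11297 genes were changed. In most real comparisons far more genes were called, and the SR9011 libraries spread more, so the simulated rates may not carry over to them. For TGFb against vehicle it recovered 76% of genes changed by log2 0.3, 96% at 0.6 and 100% at 1, and 13 of 199 called genes were unchanged, while for the interaction of CLK8 and TGFb it recovered 38% at 0.3, 90% at 0.6 and 100% at 1, with 11 of 175 called genes unchanged. A response retained to 40% was fitted with a slope of 0.392, and one retained in full with 0.983.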

Results

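RNA was sequenced from EMS404 cells, a mouse hepatic stellate cell line that carries human TLR4. Stellate cells lay down most of the scar matrix of a fibrotic liver, and TGFb is a strong inducer of that programme. The 24 libraries form 8 groups of 3 biological replicates. The groups were vehicle, TGFb, SB431542 (an inhibitor of the TGFb receptor), SR9011 (an agonist of REV-ERB), CLK8 (a compound that disturbs the dimer of CLOCK and BMAL1) and each of these compounds with TGFb. Compounds were given for 24 h, followed in the groups with TGFb by 24 h of compound with TGFb at 10 ng/mL, and the compound doses are not given in the sources used here. Nor is it given whether the groups without TGFb were kept for the second 24 h, so comparisons of groups with and without TGFb do not separate TGFb from time in culture. Expression was given as FPKM. The values summed to between 504304 and 610449 per library, and 10791 to 11011 genes per library reached 1 FPKM. Read totals are unknown, but the smallest steps between low values of 54 genes gave relative depths of 0.94 to 1.08 between libraries. The 10 most abundant genes held 5.19 to 7.46% of the summed FPKM. Changes below are log2 fold changes of FPKM + 1, which understate the change of genes near 1 FPKM, and a gene is called where its limma p after Benjamini-Hochberg adjustment over 11297 genes was under 0.05. The median standard error of a log2 fold change between groups was 0.064. Positions are on mm10, and the genes given with a position are protein coding. In a principal component plot the first component held 45.4% and the second 33% of the variance, and the replicates of each group lay together.

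**Figure D1:**
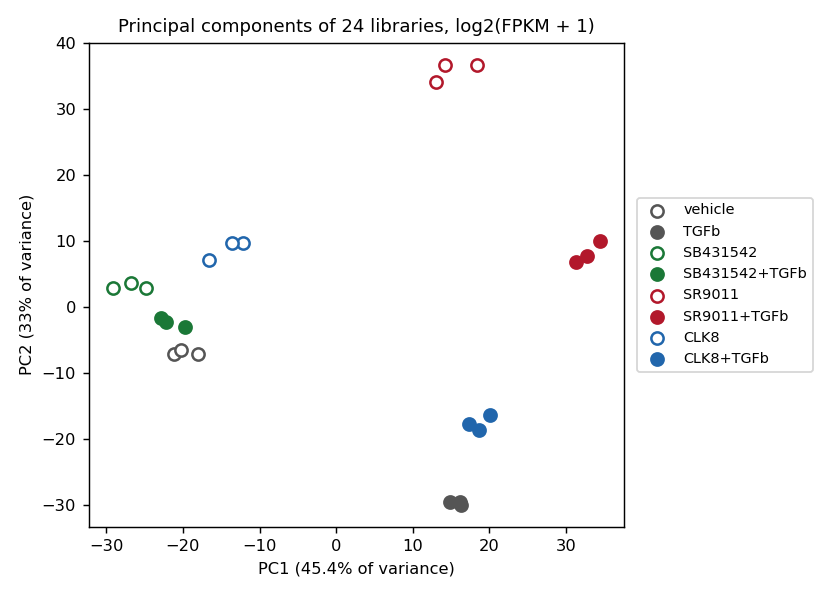
Each point is 1 of 24 libraries, placed by its scores on PC1 (x axis, 45.4% of variance) and PC2 (y axis, 33% of variance) of log2(FPKM + 1), with colour for the compound and filled points for TGFb. The 3 SB431542 libraries with TGFb lie near vehicle, whereas the SR9011 libraries lie apart from all other groups.

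TGFb against vehicle asked how the cells answered the cytokine alone. The largest rise was in Ctsw (ENSMUSG00000024910, chromosome 19, 5465043 to 5468507), which codes for a cysteine protease, from 0.090 ± 0.052 to 37.3 ± 0.515 FPKM (SD, n = 3, log2 5.14, SE 0.076, limma adjusted p = 1.55e-23). Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), the gene of the matricellular protein periostin, rose from 1.24 ± 0.171 to 41.3 ± 2.47 FPKM (log2 4.24). Pmepa1 (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533), a target and inhibitor of TGFb signalling, rose from 5.24 ± 0.383 to 71.6 ± 2.78 FPKM (log2 3.54). The other large rises were in the matrix genes Mfap4 (3.51) and Crispld2 (3.40), the ectonucleotidase gene Nt5e (3.22), the annexin gene Anxa8 (3.12) and the gelatinase gene Mmp2 (3.10). Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975), the gene of the matrix protease stromelysin, fell most, from 16.8 ± 1.64 to 0.387 ± 0.132 FPKM (log2 -3.68, SE 0.136, limma adjusted p = 1.77e-15). Large falls followed in the water channel gene Aqp1 (-3.52), the BMP target Id2 (-2.91), Ptn (-2.30), Serpind1 (-2.29), Rerg (-2.2), Tent5c (-2.17) and Lgals2 (-2.13). Of 97 named genes checked, 18 overlap another measured gene, among them Serpind1, Anxa8 and Timp1, and as the strand of the libraries is not given their values are less certain. Of 11297 genes, 2311 rose and 3888 fell, with 152 rises and 206 falls of at least 2-fold. The split depended on the scaling, with 3004 higher and 2885 lower after rescaling to TPM and 3068 higher and 3105 lower after quantile normalization.

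Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), the smooth muscle actin that marks myofibroblasts, rose from 99.9 ± 5.34 to 189 ± 12.8 FPKM (SD, n = 3, log2 0.91, limma adjusted p = 2.34e-05). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) rose from 1574 ± 70.9 to 2421 ± 194 FPKM (log2 0.62). Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), an inhibitor of matrix proteases, rose from 117 ± 10.4 to 302 ± 15.2 FPKM (log2 1.36). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), the gene of a matricellular growth factor, rose from 36 ± 4.65 to 174 ± 7.77 FPKM (log2 2.25). Smad7, which codes for a feedback inhibitor of SMAD signalling, was not called (8.38 ± 0.095 and 7.96 ± 0.509 FPKM, limma adjusted p = 0.431). Tgfb1 rose by 0.34 and Tgfbr1 was not called (limma adjusted p = 0.847).

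Of 26 gene lists tested, 13 were called with TGFb, 9 higher and 4 lower, and 1 of these calls held with an estimated correlation between genes. That was the TGFb-SMAD response, where 19 of 22 genes rose and 1 fell (median log2 0.75, camera adjusted p = 1.78e-12, 5.99e-05 with an estimated correlation), with Ldlrad4 at 2.26, Cdkn2b at 1.29 and Snai1 at 1.60. All 8 BMP-SMAD response genes fell, among them Id3 (-2.09), Id1 (-1.5) and Smad9 (-1.11) (camera adjusted p = 8.23e-07, 0.11 with an estimated correlation). Of 17 collagen genes, 14 rose, among them Col8a2 (3.04), Col5a2 (1.44) and Col5a1 (1.43), and 3 fell (camera adjusted p = 9.37e-08, 0.229 with an estimated correlation). The integrated stress response, by which cells adapt protein synthesis and amino acid supply, had 16 of 23 genes higher and 1 lower, with Nupr1 at 1.44 and Trib3 at 1.19 (camera adjusted p = 9.37e-08, 0.283 with an estimated correlation). Contractile and myofibroblast genes rose in 12 of 19 cases and fell in 3, with Itgb5 at 1.32 and Itga11 at 1.10 (camera adjusted p = 7.99e-05, 0.232 with an estimated correlation). Other matrix proteins rose in 14 of 25 and fell in 6, with Vcan at 2.61, Spp1 at 2.59 and Dcn at -2.01 (camera adjusted p = 0.000164, 0.283 with an estimated correlation). Interferon response genes fell in 19 of 24, including the immunoproteasome genes Psmb8 (-0.87) and Psmb9 (-1.10) (camera adjusted p = 0.00183, 0.507 with an estimated correlation). YAP-TEAD targets rose in 6 of 13 and fell in 2 (camera adjusted p = 0.0106, 0.33 with an estimated correlation). NRF2 targets, genes of the antioxidant defence, fell in 12 and rose in 1 of 18, with Gstm1 at -1.86 (camera adjusted p = 0.0109, 0.33 with an estimated correlation). Proliferation genes fell in 18 and rose in 1 of 31, with Ccnd1 at -1.65 (camera adjusted p = 0.0216, 0.33 with an estimated correlation). ER chaperones rose in 7 and fell in 1 of 17 (camera adjusted p = 0.0229, 0.33 with an estimated correlation). The p53 targets rose in 9 and fell in 3 of 16 (camera adjusted p = 0.0247, 0.313 with an estimated correlation). Immediate early genes rose in 5 and fell in 3 of 13 (camera adjusted p = 0.0283, 0.342 with an estimated correlation). Counts adjusted over the list alone were the same except for integrated stress response (17 higher, 1 lower), interferon response (0 higher, 20 lower) and proliferation (2 higher, 18 lower). After quantile normalization the p53, immediate early and proliferation lists were no longer called.

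**Figure D2:**
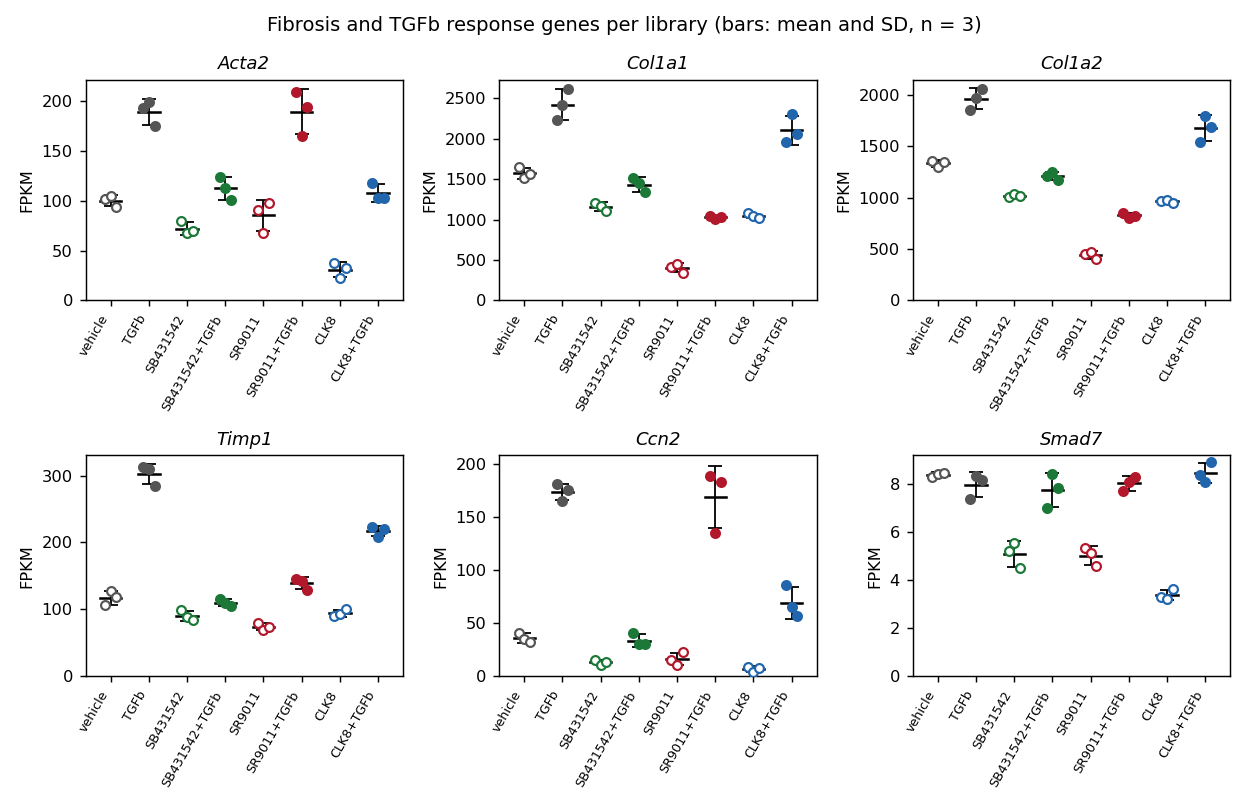
Points are FPKM (y axis) of single libraries in each group (x axis) for Acta2, Col1a1, Col1a2, Timp1, Ccn2 and Smad7, and bars are the mean and SD of 3 libraries. Ccn2 rose from 36 FPKM in vehicle to 174 with TGFb, and stood at 33.5 with SB431542 and TGFb, 169 with SR9011 and TGFb and 69.3 with CLK8 and TGFb.

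SB431542 against vehicle asked what the receptor inhibitor changed without added TGFb. Ccn2 fell from 36 ± 4.65 to 13.2 ± 2.09 FPKM (SD, n = 3, log2 -1.39, SE 0.258, limma adjusted p = 0.000938). Other large falls were in Pmepa1 (-1.17), the sodium pump subunit gene Atp1b1 (-1.15), Fam210b (-1.13), the hormone gene Fgf21 (-1.10), Mmp2 (-1.10) and Skil (-1.09), a repressor of SMAD signalling. Tnxb, the gene of the matrix protein tenascin X, rose most, from 2.44 ± 0.247 to 7.05 ± 0.124 FPKM (log2 1.23, SE 0.070, limma adjusted p = 4.77e-11). Rises followed in Mmp3 (1.19), Gpnmb (1.19), Olfr1033 (1.16), Apoe (1.10), Scara5 (1.07), Aldh3a1 (1.05) and the chemokine gene Cxcl13 (1.04). Acta2 fell to 72 ± 6.23 FPKM (log2 -0.47, limma adjusted p = 0.030), Col1a1 to 1161 ± 52.1 (-0.44), Timp1 to 90.2 ± 7.24 (-0.37) and Smad7 to 5.08 ± 0.524 (-0.63). In all, 1339 genes rose and 571 fell, with 11 rises and 9 falls of at least 2-fold, and quantile normalization gave 937 higher and 862 lower.

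Lists called with SB431542 numbered 14 of 26, 3 higher and 11 lower, and 4 calls held with an estimated correlation. Collagens fell in 10 of 17 genes, with Col5a2 at -0.75 and Col4a2 at -0.50 (camera adjusted p = 9.47e-12, 0.0443 with an estimated correlation). The TGFb-SMAD response fell in 11 and rose in 2 of 22 (camera adjusted p = 2.32e-11, 0.000126 with an estimated correlation). Contractile and myofibroblast genes fell in 9 of 19 (camera adjusted p = 1.28e-09, 0.0443 with an estimated correlation), and AhR targets, genes of the response to aryl hydrocarbons, rose in 5 of 6 (camera adjusted p = 0.00205, 0.0443 with an estimated correlation). Integrated stress response genes fell in 12 of 23, with Nupr1 at -0.58 and Aldh1l2 at -0.53 (camera adjusted p = 4.11e-09, 0.145 with an estimated correlation). Other matrix proteins fell in 12 and rose in 1 of 25, with Bgn at -0.93 and Fbln5 at -0.74 (camera adjusted p = 6.66e-08, 0.0766 with an estimated correlation). Inflammatory and chemokine genes fell in 8 and rose in 1 of 18, with Ptgs2 at -0.56 (camera adjusted p = 6.18e-05, 0.102 with an estimated correlation). Matrix crosslinking and turnover genes fell in 10 and rose in 6 of 29 (camera adjusted p = 0.00308, 0.102 with an estimated correlation). YAP-TEAD targets fell in 5 and rose in 1 of 13 (camera adjusted p = 0.00498, 0.334 with an estimated correlation). NRF2 targets rose in 8 of 18, with Ftl1 at 0.40 (camera adjusted p = 0.0173, 0.374 with an estimated correlation). Autophagy and lysosome genes rose in 7 of 18 (camera adjusted p = 0.00308, 0.208 with an estimated correlation). Few members fell on their own in the called lists of glycolysis (1 of 17, camera adjusted p = 0.00229, 0.548 with an estimated correlation), ER chaperones (1 of 17, camera adjusted p = 0.0274, 0.374 with an estimated correlation) and immediate early genes (2 of 13, camera adjusted p = 0.0339, 0.396 with an estimated correlation). These 3 calls were lost after quantile normalization. Adjusted over the list alone, the counts were the same except for TGFb-SMAD response (2 higher, 13 lower), contractile and myofibroblast (0 higher, 13 lower), AhR targets (5 higher, 1 lower), integrated stress response (1 higher, 14 lower), other matrix proteins (2 higher, 13 lower), inflammatory and chemokine (2 higher, 10 lower), matrix crosslinking and turnover (8 higher, 14 lower), NRF2 targets (9 higher, 0 lower), autophagy and lysosome (9 higher, 0 lower) and glycolysis (0 higher, 0 lower).

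SR9011 against vehicle asked what the REV-ERB agonist changed on its own. Car6 (ENSMUSG00000028972, chromosome 4, 150187015 to 150201332), the gene of a secreted carbonic anhydrase, rose most, from 0.377 ± 0.038 to 49.4 ± 9.88 FPKM (SD, n = 3, log2 5.17, SE 0.155, limma adjusted p = 3.12e-17). Rises followed in Avil (4.63), which shares sequence with Tsfm in the annotation, the glycosyltransferase gene B4galnt2 (3.31), Cdsn (3.23), the collagenase gene Mmp13 (3.06), Cox6a2 (3.03), Angptl6 (3.03) and Gpnmb (2.94). Angptl7, a secreted protein gene that lies within Mtor, fell most, from 23.3 ± 1.6 to 0.183 ± 0.025 FPKM (log2 -4.36, SE 0.196, limma adjusted p = 1.57e-13). Lrrn4 (-3.64), the chemokine gene Ccl2 (-3.58), the alarmin gene Il33 (-3.11), Lgals2 (-3.10), Ptn (-3.08), Crip1 (-2.98) and the hypoxia-induced Car9 (-2.97) also fell. Col1a1 fell from 1574 ± 70.9 to 405 ± 58.2 FPKM (log2 -1.97), as did Col1a2 (-1.59). Acta2 was not called (85.2 ± 15.6 FPKM, limma adjusted p = 0.142), and Tgfb1 rose by 1.10. In all, 4602 genes rose and 3199 fell, with 315 rises and 357 falls of at least 2-fold, whereas TPM gave 3723 higher and 3775 lower and quantile normalization 3992 and 3688. The 3 SR9011 libraries lay further from their group mean than other libraries (mean squared deviation 0.0192, 0.0119 and 0.00925, against 0.00346 to 0.00891), and 7863 genes were called without SR9011 replicate 1, against 7801 with it. The main fit shares 1 spread over all groups, so p values with SR9011 may be too small. A fit of the compared groups alone called fewer genes, 6832. It called 3668 for TGFb within SR9011, against 5114 in the main fit, and 3128 for the interaction, against 3607.

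With SR9011, 19 of 26 lists were called, 5 higher and 14 lower, and the calls for inflammatory and chemokine genes and for proliferation held with an estimated correlation. Inflammatory and chemokine genes fell in 17 of 18 (median log2 -1.52, camera adjusted p = 1.66e-10, 0.0312 with an estimated correlation), with Cxcl5 at -1.89 and Cxcl12 at -1.80. Proliferation genes fell in 27 and rose in 2 of 31, with Bub1b at -0.77 and Tyms at -0.62 (camera adjusted p = 7.93e-09, 0.0312 with an estimated correlation). The integrated stress response rose in 22 of 23 genes (median log2 1.06), with Ddit3 at 2.67, Trib3 at 2.30 and Atf3 at 1.88 (camera adjusted p = 1.32e-07, 0.153 with an estimated correlation). NRF2 targets rose in 16 of 18, with Nqo1 at 1.70 and Ftl1 at 1.67 (camera adjusted p = 2.46e-05, 0.126 with an estimated correlation). The p53 targets rose in 12 and fell in 4 of 16, with Trp53inp1 at 1.78 and Cdkn1a at 1.54 (camera adjusted p = 0.0196, 0.179 with an estimated correlation). Cholesterol synthesis genes fell in 22 of 23, with Hmgcs1 at -1.14 (camera adjusted p = 2.60e-09, 0.153 with an estimated correlation). Glycolysis genes fell in 16 of 17, with Ldha at -1.29 (camera adjusted p = 6.71e-07, 0.252 with an estimated correlation). Fatty acid synthesis genes fell in 7 and rose in 2 of 13, with Elovl6 at -1.5 (camera adjusted p = 0.00863, 0.271 with an estimated correlation). Among matrix groups, collagens fell in 14 of 17 (camera adjusted p = 1.13e-08, 0.11 with an estimated correlation). Other matrix proteins fell in 21 and rose in 1 of 25, with Thbs1 at -2.42 and Spp1 at -2.52 (camera adjusted p = 5.04e-09, 0.0771 with an estimated correlation), and crosslinking and turnover genes fell in 20 and rose in 6 of 29 (camera adjusted p = 0.000709, 0.104 with an estimated correlation). Contractile genes fell in 14 and rose in 2 of 19, with Cnn1 at -1.46 (camera adjusted p = 0.000409, 0.153 with an estimated correlation). Interferon response genes fell in 19 and rose in 1 of 24, with Cxcl10 at -2.88 (camera adjusted p = 5.31e-06, 0.271 with an estimated correlation). Autophagy and lysosome genes rose in 12 and fell in 3 of 18, with Ctsl at 1.82 (camera adjusted p = 0.00231, 0.153 with an estimated correlation). ER chaperones fell in 10 and rose in 4 of 17, with Calr at -1.01 and Herpud1 at 1.21 (camera adjusted p = 0.00553, 0.179 with an estimated correlation). Quiescent stellate cell genes fell in 8 and rose in 3 of 13, with Hand2 at -1.36 (camera adjusted p = 0.0237, 0.271 with an estimated correlation). BMP-SMAD genes fell in 6 and rose in 1 of 8 (camera adjusted p = 0.0331, 0.271 with an estimated correlation) and portal fibroblast and mesothelial markers fell in 7 and rose in 1 of 8 (camera adjusted p = 0.00231, 0.153 with an estimated correlation). The counts adjusted over the list alone were the same except for proliferation (2 higher, 28 lower), collagens (0 higher, 15 lower), other matrix proteins (2 higher, 21 lower) and core clock (16 higher, 1 lower). Quantile normalization removed the calls for the BMP-SMAD and quiescent stellate cell lists.

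CLK8 against vehicle asked what the disruptor of the CLOCK and BMAL1 dimer changed on its own. Vcan (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509), the gene of the proteoglycan versican, rose most, from 1.91 ± 0.19 to 18.5 ± 0.604 FPKM (SD, n = 3, log2 2.75, SE 0.069, limma adjusted p = 2.01e-18). Rises followed in the lubricin gene Prg4 (2.56), Gpnmb (2.45), the antiprotease gene Slpi (2.12), Aldh3a1 (1.99), Ly6a (1.88), Frmd5 (1.77) and Dtx4 (1.75). Angptl7 fell most, from 23.3 ± 1.6 to 1.25 ± 0.384 FPKM (log2 -3.44, SE 0.196, limma adjusted p = 4.72e-11). Falls followed in Ccn2 (-2.33), the acute phase gene Saa3 (-2.33), the hyaluronan-degrading Cemip (-2.23), the contractile gene Tagln (-2.18), Igfbp7 (-2.15), the mesothelial gene Upk3b (-2.10) and Ccl2 (-1.96). Acta2 fell from 99.9 ± 5.34 to 30.9 ± 7.38 FPKM (log2 -1.69, SE 0.145, limma adjusted p = 1.18e-08), as did Col1a1 (-0.58), Timp1 (-0.31) and Smad7 (-1.10). In all, 3425 genes rose and 1534 fell, with 59 rises and 86 falls of at least 2-fold, and quantile normalization gave 2385 higher and 2197 lower.

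With CLK8, 14 of 26 lists were called, 3 higher and 11 lower, and 4 calls held with an estimated correlation. Contractile and myofibroblast genes fell in 16 of 19, with Myl9 at -1.58 and Cnn1 at -1.43 (camera adjusted p = 1.52e-14, 0.00718 with an estimated correlation). BMP-SMAD genes fell in 8 of 8 (camera adjusted p = 3.30e-08, 0.0265 with an estimated correlation). TGFb-SMAD response genes fell in 12 and rose in 5 of 22 (camera adjusted p = 0.000215, 0.0135 with an estimated correlation). AhR targets rose in 6 of 6 cases (median log2 0.98, camera adjusted p = 1.59e-06, 0.00518 with an estimated correlation), with Cyp1b1 at 1.18 and Cyp1a1 at 1.08. Collagens fell in 13 and rose in 1 of 17, with Col8a2 at -1.38 (camera adjusted p = 5.08e-10, 0.0638 with an estimated correlation). Other matrix proteins fell in 15 and rose in 4 of 25, with Fn1 at -0.89 (camera adjusted p = 1.04e-05, 0.123 with an estimated correlation). Crosslinking and turnover genes fell in 15 and rose in 7 of 29 (camera adjusted p = 0.000778, 0.0693 with an estimated correlation). Glycolysis genes fell in 14 of 17, with Ldha at -0.98 (camera adjusted p = 8.36e-08, 0.286 with an estimated correlation). Fatty acid synthesis genes rose in 10 of 13, with Scd1 at 0.81 (camera adjusted p = 0.00161, 0.274 with an estimated correlation). Inflammatory and chemokine genes fell in 11 and rose in 4 of 18, with Csf1 at -1.01 and Ptgs2 at 0.91 (camera adjusted p = 0.00015, 0.123 with an estimated correlation). YAP-TEAD targets fell in 8 and rose in 2 of 13 (camera adjusted p = 0.00022, 0.145 with an estimated correlation). Portal fibroblast and mesothelial markers fell in 5 and rose in 2 of 8, with Wt1 at -0.80 (camera adjusted p = 0.00253, 0.145 with an estimated correlation). Autophagy and lysosome genes rose in 11 and fell in 4 of 18 (camera adjusted p = 0.0271, 0.308 with an estimated correlation). Proliferation genes fell in 8 and rose in 6 of 31 (camera adjusted p = 0.026, 0.308 with an estimated correlation), a call lost after quantile normalization. With p adjusted over the list alone, counts were the same except for contractile and myofibroblast (0 higher, 17 lower), TGFb-SMAD response (5 higher, 13 lower), other matrix proteins (5 higher, 15 lower) and matrix crosslinking and turnover (7 higher, 16 lower).

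SB431542 with TGFb against TGFb asked how far receptor inhibition changed cells under the cytokine. Mmp3 rose most, from 0.387 ± 0.132 to 25.5 ± 1.72 FPKM (SD, n = 3, log2 4.26, SE 0.136, limma adjusted p = 1.04e-16). It was followed by Aqp1 (3.78), Id2 (3.06), Gpnmb (2.63), Apoe (2.59), Mmp13 (2.44), Tnxb (2.43) and Ahsg (2.39). Ctsw fell most, from 37.3 ± 0.515 to 0.127 ± 0.084 FPKM (log2 -5.09, SE 0.076, limma adjusted p = 1.70e-23). Next came Postn (-4.22), Mfap4 (-3.89), Pmepa1 (-3.88), Col8a2 (-3.58), Fgf21 (-3.49), Crispld2 (-3.40) and Nt5e (-3.39). Acta2 fell from 189 ± 12.8 to 112 ± 11.7 FPKM (log2 -0.75), Col1a1 from 2421 ± 194 to 1435 ± 87.6 (-0.75), Timp1 from 302 ± 15.2 to 109.9 ± 5.03 (-1.45) and Ccn2 from 174 ± 7.77 to 33.5 ± 6.04 (-2.36). In all, 4328 genes rose and 2412 fell, with 286 rises and 173 falls of at least 2-fold, and quantile normalization gave 3315 higher and 3450 lower. Of 26 lists, 13 were called, 4 higher and 9 lower, and the TGFb-SMAD response alone held with an estimated correlation, with 19 of 22 genes lower and 1 higher (median log2 -0.70, camera adjusted p = 5.49e-12, 7.69e-05 with an estimated correlation). BMP-SMAD genes rose in 8 of 8, with Id3 at 2.15 (camera adjusted p = 8.97e-06, 0.177 with an estimated correlation). Interferon response genes rose in 19 of 24, with Psmb9 at 1.48 (camera adjusted p = 0.00335, 0.532 with an estimated correlation). NRF2 targets rose in 12 and fell in 1 of 18 (camera adjusted p = 0.00866, 0.299 with an estimated correlation) and autophagy and lysosome genes rose in 11 and fell in 2 of 18, with Ctsb at 1.02 (camera adjusted p = 0.0259, 0.30 with an estimated correlation). Collagens fell in 14 and rose in 3 of 17 (camera adjusted p = 2.14e-08, 0.177 with an estimated correlation). Integrated stress response genes fell in 18 and rose in 1 of 23 (camera adjusted p = 5.29e-08, 0.269 with an estimated correlation). Contractile genes fell in 13 and rose in 3 of 19 (camera adjusted p = 3.93e-05, 0.197 with an estimated correlation). Other matrix proteins fell in 13 and rose in 5 of 25 (camera adjusted p = 0.000185, 0.269 with an estimated correlation). ER chaperones fell in 8 and rose in 1 of 17 (camera adjusted p = 0.00669, 0.269 with an estimated correlation). YAP-TEAD targets fell in 6 and rose in 4 of 13 (camera adjusted p = 0.0259, 0.366 with an estimated correlation). Crosslinking and turnover genes fell in 14 and rose in 9 of 29 (camera adjusted p = 0.0347, 0.269 with an estimated correlation). The p53 targets fell in 9 and rose in 4 of 16 (camera adjusted p = 0.0347, 0.299 with an estimated correlation). These counts, adjusted over the list alone, were the same except for other matrix proteins (6 higher, 13 lower). The YAP-TEAD, crosslinking and p53 lists were no longer called after quantile normalization.

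SR9011 with TGFb against TGFb asked what the agonist changed in cells given the cytokine. Car6 rose most, from 0.78 ± 0.026 to 22 ± 7.82 FPKM (SD, n = 3, log2 3.64, SE 0.155, limma adjusted p = 1.33e-14). Rises followed in Gpnmb (3.49), Avil (3.0), B4galnt2 (2.67), Uap1l1 (2.52), Plxdc1 (2.35), the BMP antagonist gene Nbl1 (2.32) and Klf15 (2.30). Il33 fell most, from 16.2 ± 0.877 to 0.64 ± 0.141 FPKM (log2 -3.40, SE 0.103, limma adjusted p = 2.36e-17). Falls followed in Lrrn4 (-2.91), the chemokine genes Cxcl10 (-2.78) and Ccl2 (-2.55), Car9 (-2.66), the osteopontin gene Spp1 (-2.60), Plac1 (-2.52) and the gelatinase gene Mmp9 (-2.41). Col1a1 fell from 2421 ± 194 to 1027 ± 20.3 FPKM (log2 -1.23), and Col1a2 (-1.24) and Timp1 (-1.12) fell too. Acta2 (189 ± 22.7 FPKM, limma adjusted p = 0.986) and Ccn2 (169 ± 29.5 FPKM, limma adjusted p = 0.867) were not called. In all, 4158 genes rose and 2713 fell, with 231 rises and 192 falls of at least 2-fold, whereas TPM gave 3078 higher and 3645 lower and quantile normalization 3388 and 3563. Of 26 lists, 13 were called, 3 higher and 10 lower, and inflammatory and chemokine genes alone held with an estimated correlation, with 17 of 18 lower (median log2 -0.98, camera adjusted p = 5.77e-12, 0.0197 with an estimated correlation) and Il6 at -2.08. Collagens fell in 14 and rose in 1 of 17, with Col5a3 at -1.74 (camera adjusted p = 3.34e-08, 0.129 with an estimated correlation). Other matrix proteins fell in 17 and rose in 2 of 25 (camera adjusted p = 1.26e-06, 0.129 with an estimated correlation) and contractile genes fell in 12 and rose in 2 of 19 (camera adjusted p = 0.000704, 0.232 with an estimated correlation). Portal fibroblast and mesothelial markers fell in 6 and rose in 1 of 8 (camera adjusted p = 0.00532, 0.232 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 23 (camera adjusted p = 5.59e-08, 0.26 with an estimated correlation). Glycolysis genes fell in 15 of 17 (camera adjusted p = 4.88e-06, 0.335 with an estimated correlation) and fatty acid synthesis genes fell in 8 and rose in 1 of 13 (camera adjusted p = 0.00573, 0.325 with an estimated correlation). Interferon response genes fell in 18 and rose in 4 of 24 (camera adjusted p = 1.80e-05, 0.354 with an estimated correlation). Proliferation genes fell in 23 and rose in 2 of 31 (camera adjusted p = 4.82e-05, 0.129 with an estimated correlation). NRF2 targets rose in 13 of 18 (camera adjusted p = 5.95e-05, 0.151 with an estimated correlation). Autophagy and lysosome genes rose in 13 and fell in 3 of 18 (camera adjusted p = 8.88e-05, 0.129 with an estimated correlation). Integrated stress response genes rose in 11 and fell in 1 of 23, with Ddit3 at 1.58 (camera adjusted p = 0.0473, 0.598 with an estimated correlation). List by list, counts adjusted over the list alone were the same.

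CLK8 with TGFb against TGFb asked the same of the dimer disruptor. Gpnmb rose most, from 0.757 ± 0.055 to 7.63 ± 1.46 FPKM (SD, n = 3, log2 2.28, SE 0.108, limma adjusted p = 5.46e-13). Rises followed in the complement gene C4b (1.97), Vcan (1.86), Xdh (1.82), Aldh3a1 (1.79), Mmp3 (1.66), the metallothionein gene Mt2 (1.64) and Klf15 (1.59). Saa3 fell most, from 68 ± 9.4 to 15.2 ± 1.18 FPKM (log2 -2.09, SE 0.248, limma adjusted p = 2.94e-06). Falls followed in Cemip (-1.90), Map3k7cl (-1.87), Upk3b (-1.86), Plac1 (-1.65), Lrrn4 (-1.54), Ccl2 (-1.48) and Lgals2 (-1.44). Acta2 fell from 189 ± 12.8 to 108 ± 8.81 FPKM (log2 -0.81, limma adjusted p = 0.000172), Ccn2 from 174 ± 7.77 to 69.3 ± 14.8 (-1.34) and Timp1 from 302 ± 15.2 to 217 ± 7.82 (-0.48). Col1a1 was not called (2109 ± 179 FPKM, limma adjusted p = 0.0554). In all, 3130 genes rose and 1508 fell, with 43 rises and 36 falls of at least 2-fold, and quantile normalization gave 2241 higher and 2277 lower. Of 26 lists, 14 were called, 5 higher and 9 lower, and AhR targets alone held with an estimated correlation, with 6 of 6 higher (median log2 1.24, camera adjusted p = 3.20e-09, 0.000553 with an estimated correlation) and Cyp1a1 at 1.58. Cholesterol synthesis genes fell in 18 and rose in 1 of 23, with Lss at -0.75, Mvd at -0.62 and Fdps at -0.56 (camera adjusted p = 1.95e-10, 0.212 with an estimated correlation). Collagens fell in 11 of 17 (camera adjusted p = 6.66e-08, 0.132 with an estimated correlation). Contractile genes fell in 12 and rose in 1 of 19, with Tpm1 at -0.65 (camera adjusted p = 2.86e-06, 0.132 with an estimated correlation). Inflammatory and chemokine genes fell in 10 and rose in 1 of 18 (camera adjusted p = 1.98e-05, 0.132 with an estimated correlation). Portal fibroblast and mesothelial markers fell in 6 and rose in 1 of 8, with Upk1b at -1.06 (camera adjusted p = 0.000411, 0.132 with an estimated correlation). Autophagy and lysosome genes rose in 11 and fell in 2 of 18 (camera adjusted p = 0.00422, 0.275 with an estimated correlation). Immediate early genes rose in 8 and fell in 1 of 13, with Fos at 1.10 (camera adjusted p = 0.00609, 0.328 with an estimated correlation). Quiescent stellate cell genes rose in 9 of 13, with Gata4 at 0.44 (camera adjusted p = 0.0169, 0.384 with an estimated correlation). Interferon response genes rose in 15 and fell in 1 of 24 (camera adjusted p = 0.0177, 0.766 with an estimated correlation). Glycolysis genes fell in 4 and rose in 1 of 17 (camera adjusted p = 0.00422, 0.686 with an estimated correlation). YAP-TEAD targets fell in 6 and rose in 3 of 13 (camera adjusted p = 0.0169, 0.384 with an estimated correlation). ER chaperones fell in 6 and rose in 3 of 17 (camera adjusted p = 0.0184, 0.384 with an estimated correlation), and proliferation genes fell in 13 and rose in 8 of 31 (camera adjusted p = 0.0298, 0.384 with an estimated correlation). These last 4 calls were lost after quantile normalization. Here the counts adjusted over the list alone were the same except for collagens (0 higher, 13 lower), contractile and myofibroblast (2 higher, 13 lower), inflammatory and chemokine (1 higher, 11 lower), immediate early (9 higher, 1 lower), quiescent stellate cell (10 higher, 1 lower), interferon response (18 higher, 1 lower) and glycolysis (1 higher, 3 lower).

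**Figure D3:**
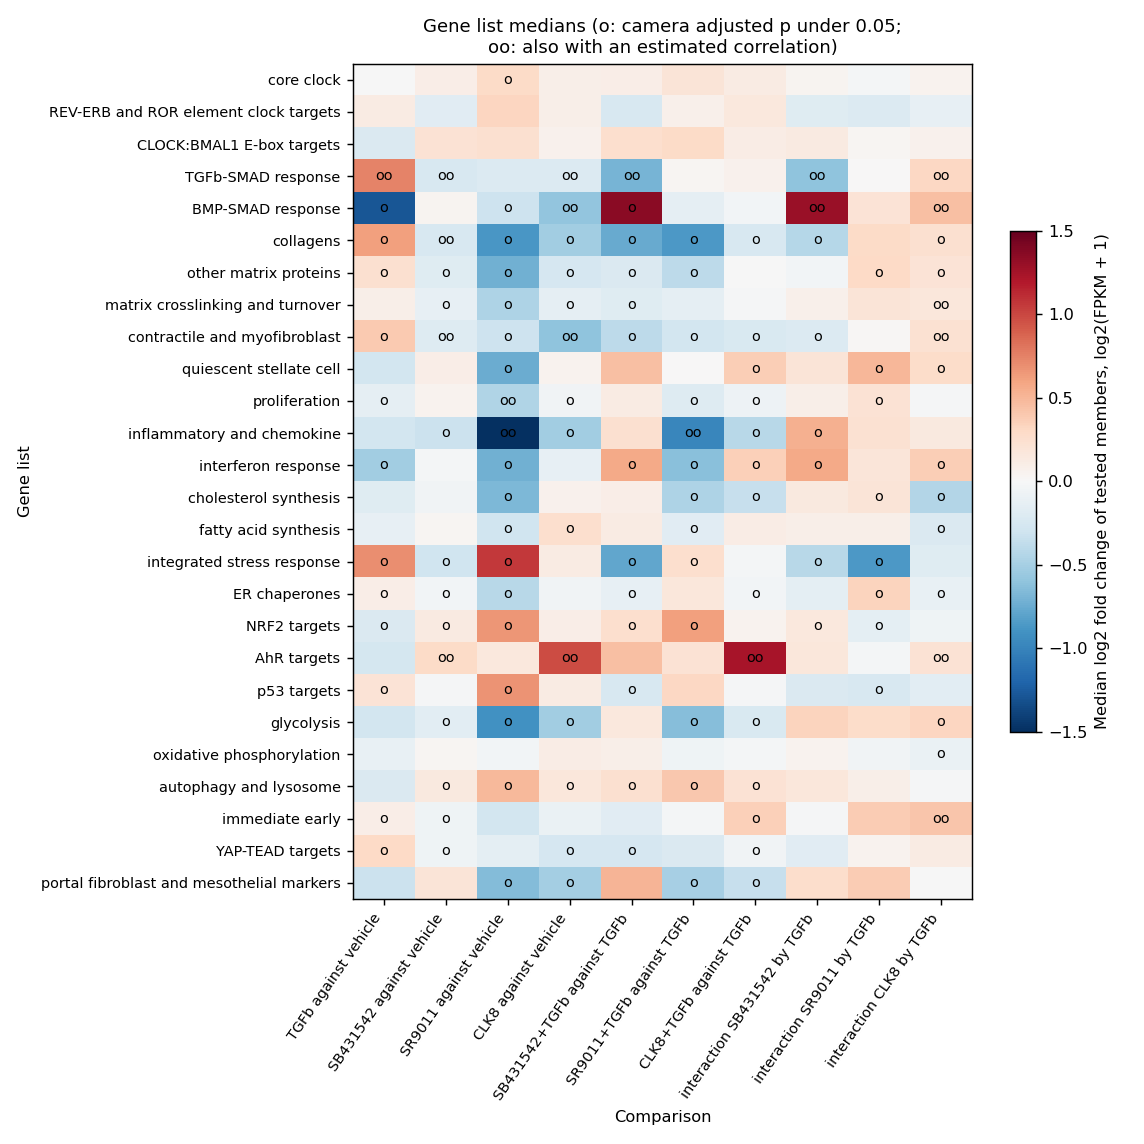
Colours give the median log2 fold change, on log2(FPKM + 1), of the tested members of 26 gene lists (y axis) in 10 comparisons (x axis), with 1 circle where camera called the list and a pair where the call also held with an estimated correlation. The BMP-SMAD median was -1.29 with TGFb against vehicle and 1.35 with SB431542 and TGFb against TGFb, and the AhR target median was 0.98 with CLK8.

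The response to TGFb in the presence of each compound was measured against the same compound alone. With SB431542 present, TGFb raised 227 genes and lowered 266, with 3 rises and 0 falls of at least 2-fold, and TPM gave 213 higher and 145 lower. Ccn2 rose from 13.2 ± 2.09 to 33.5 ± 6.04 FPKM (SD, n = 3, log2 1.28, limma adjusted p = 0.0074), Acta2 by 0.63 and Col1a1 by 0.30. The count of 493 genes depended on single libraries, with 199 without SB431542 replicate 3, 244 without SB431542+TGFb replicate 1 and 243 without SB431542+TGFb replicate 2. With SR9011 present, 1616 genes rose and 3498 fell (TPM 1882 and 2426, quantile normalization 2052 and 2697). Here Ccn2 rose from 16.1 ± 5.87 to 169 ± 29.5 FPKM (log2 3.36), Acta2 by 1.15 and Col1a1 by 1.35. With CLK8 present, 1951 genes rose and 3914 fell (TPM 2972 and 2456, quantile normalization 2727 and 3005). Ccn2 then rose from 6.66 ± 2.6 to 69.3 ± 14.8 FPKM (log2 3.24), Acta2 by 1.79 and Col1a1 by 1.0. Smad7, not called with TGFb alone, rose with each compound present, by 0.52 with SB431542, 0.59 with SR9011 and 1.11 with CLK8. These rises started from low levels with the compound alone (3.21 to 5.54 FPKM per library). With compound and TGFb it stood at 7.01 to 8.89 FPKM, near vehicle (8.27 to 8.45) and TGFb alone (7.38 to 8.33).

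The TGFb-SMAD response was called higher under TGFb with SB431542 present (10 of 22 genes higher and 2 lower, camera adjusted p = 3.90e-14, 2.71e-05 with an estimated correlation). The same was so with SR9011 (18 of 22 higher and 2 lower, camera adjusted p = 4.08e-17, 7.74e-06 with an estimated correlation) and with CLK8 (20 and 2, camera adjusted p = 2.67e-16, 1.07e-05 with an estimated correlation). Contractile genes rose in 5 of 19 with SB431542 (camera adjusted p = 3.89e-11, 0.0186 with an estimated correlation), in 14 with SR9011, where 1 fell (camera adjusted p = 6.14e-10, 0.0228 with an estimated correlation), and in 17 with CLK8, where 2 fell (camera adjusted p = 1.18e-11, 0.0207 with an estimated correlation). Other matrix proteins rose in 9 of 25 with SB431542 (camera adjusted p = 5.89e-12, 0.0206 with an estimated correlation), in 17 with SR9011, where 3 fell (camera adjusted p = 3.60e-12, 0.0228 with an estimated correlation), and in 17 with CLK8, where 4 fell (camera adjusted p = 3.72e-09, 0.0462 with an estimated correlation). Immediate early genes rose in 6 of 13 with SB431542 (camera adjusted p = 5.89e-12, 0.0116 with an estimated correlation) and in 11 with CLK8, where 1 fell (camera adjusted p = 1.42e-07, 0.0462 with an estimated correlation). Matrix crosslinking and turnover genes rose in 17 and fell in 8 of 29 with CLK8 (camera adjusted p = 0.000173, 0.0462 with an estimated correlation). With SR9011, collagens rose in 13 and fell in 3 of 17 (camera adjusted p = 3.79e-11, 0.0421 with an estimated correlation), and ER chaperones rose in 16 of 17, with Calr at 0.83 and Pdia4 at 0.69 (camera adjusted p = 9.08e-14, 0.00442 with an estimated correlation). NRF2 targets fell in 16 of 18 with SR9011 (camera adjusted p = 2.71e-07, 0.0421 with an estimated correlation). BMP-SMAD genes fell in 8 of 8 with SR9011 (camera adjusted p = 1.78e-06, 0.0421 with an estimated correlation) and in 6 of 8 with CLK8, where 2 rose (camera adjusted p = 0.0154, 0.314 with an estimated correlation). They were not called with SB431542 (camera adjusted p = 0.695, 0.844 with an estimated correlation). With CLK8, cholesterol synthesis genes fell in 22 of 23, with Mvd at -0.78 and Mvk at -0.64 (camera adjusted p = 1.34e-08, 0.24 with an estimated correlation). Adjusted over the list alone, counts with SB431542 were the same except for TGFb-SMAD response (11 higher, 2 lower), contractile and myofibroblast (14 higher, 0 lower), other matrix proteins (10 higher, 0 lower) and immediate early (7 higher, 0 lower). With SR9011 they were the same except for contractile and myofibroblast (15 higher, 1 lower). With CLK8 they were the same except for immediate early (12 higher, 1 lower), matrix crosslinking and turnover (18 higher, 8 lower) and cholesterol synthesis (0 higher, 23 lower). In all, 11 lists were called with SB431542, 11 with SR9011 and 14 with CLK8, and 4, 7 and 5 of these calls held with an estimated correlation. With the replicate number as a block, NRF2 targets lost their call with SB431542 (camera adjusted p = 0.061).

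Over the 358 genes that TGFb alone changed at least 2-fold, the slope of the response with a compound on the response without it was 0.136 ± 0.03 with SB431542, 0.717 ± 0.011 with SR9011 and 0.943 ± 0.013 with CLK8 (SD, n = 3 libraries with compound and TGFb). It was 0.986 in simulations with an equal response. Of the 358, 105 genes were called in the same direction with SB431542 present, 314 with SR9011 and 352 with CLK8. Id2, for example, fell with TGFb alone (-2.91), with SR9011 present (-2.66) and with CLK8 present (-2.49), while it stood at 53.2 ± 7.27 and 51.6 ± 2.84 FPKM without and with TGFb under SB431542 (limma adjusted p = 0.901). Postn rose by 4.24 with TGFb alone, 3.58 with SR9011 and 3.88 with CLK8 present. Across genes, which are not independent replicates, the effect of a compound without TGFb correlated with its effect under TGFb with r = 0.611 for SB431542, 0.816 for SR9011 and 0.738 for CLK8. Genes called in the same direction both times numbered 1556 for SB431542 (513 higher and 122 lower would be shared by independent lists), 5284 for SR9011 (1694 and 768) and 3033 for CLK8 (949 and 205).

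**Figure D4:**
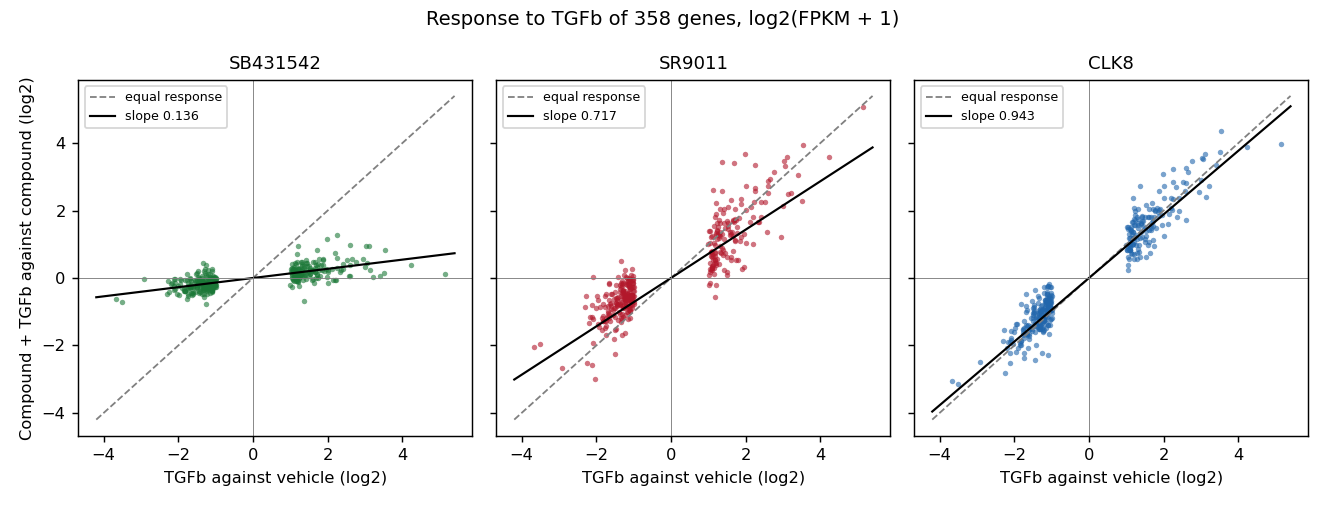
Each point is 1 of 358 genes, with the log2 fold change of TGFb against vehicle on the x axis and that of compound with TGFb against the compound on the y axis, a dashed line for an equal response and a solid line for the fitted slope. The slope was 0.136 with SB431542, 0.717 with SR9011 and 0.943 with CLK8.

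Clock genes were read in every comparison because SR9011 and CLK8 act on clock proteins, and a selection is given here, mostly against vehicle. The 24 libraries hold no time series, so these values do not describe the timing of clock genes. Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960) rose with SR9011 from 7.65 ± 0.511 to 16.9 ± 0.429 FPKM (SD, n = 3, log2 1.05, SE 0.060, limma adjusted p = 4.17e-13). Under TGFb it rose from 6.94 ± 0.381 to 17.4 ± 0.809 FPKM (1.21), and was not called with CLK8 (limma adjusted p = 0.944). Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), which codes for REV-ERB alpha, rose from 2.13 ± 0.362 FPKM to 5.61 ± 0.359 with SR9011 (1.08) and 4.26 ± 0.471 with CLK8 (0.75). Thra, which overlaps it on the opposite strand, fell with SR9011 (-0.32) and was not called with CLK8 (limma adjusted p = 0.898). Nr1d2 rose by 0.66 with SR9011 and 0.51 with CLK8. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the gene of BMAL1 and a target of REV-ERB repression, rose with TGFb from 6.3 ± 0.149 to 11.2 ± 0.334 FPKM (0.74) and with SR9011 to 7.77 ± 0.39 (0.26), and was not called with CLK8 (limma adjusted p = 0.396). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a direct target of CLOCK and BMAL1, fell with TGFb from 7.83 ± 0.994 to 2.48 ± 0.257 FPKM (-1.34), was not called with SR9011 (limma adjusted p = 0.639) and rose by 0.26 with CLK8 and 0.60 with SB431542. With TGFb, Per3 (-0.62), Per2 (-0.42) and Cry2 (-0.28) fell, while Clock (limma adjusted p = 0.293) and Cry1 (limma adjusted p = 0.659) were not called. Per2 fell with SR9011 (-0.32) and CLK8 (-0.42), Clock (0.50) and Cry1 (0.36) rose with SR9011, and Cry1 (-0.29) and Cry2 (-0.30) fell with CLK8. SB431542 against vehicle raised Nr1d1 (0.40) and lowered Arntl (-0.24). Per3 lies within Camta1 and Dbp shares bases with Sphk2, so their values are less certain. With SR9011, 15 of 22 core clock genes rose and 1 fell (camera adjusted p = 0.0209, 0.153 with an estimated correlation). With the agonist, 5 of 5 REV-ERB and ROR element targets rose without a list call (camera adjusted p = 0.13, 0.199 with an estimated correlation). CLOCK:BMAL1 E-box targets were not called with CLK8, with 5 of 15 higher and 3 lower (camera adjusted p = 0.881, 0.949 with an estimated correlation). Nor was the core clock list, with 10 of 22 higher and 4 lower (camera adjusted p = 0.618, 0.788 with an estimated correlation). Adjusted over the list alone, 16 core clock genes rose with SR9011 and the other counts were the same.

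**Figure D5:**
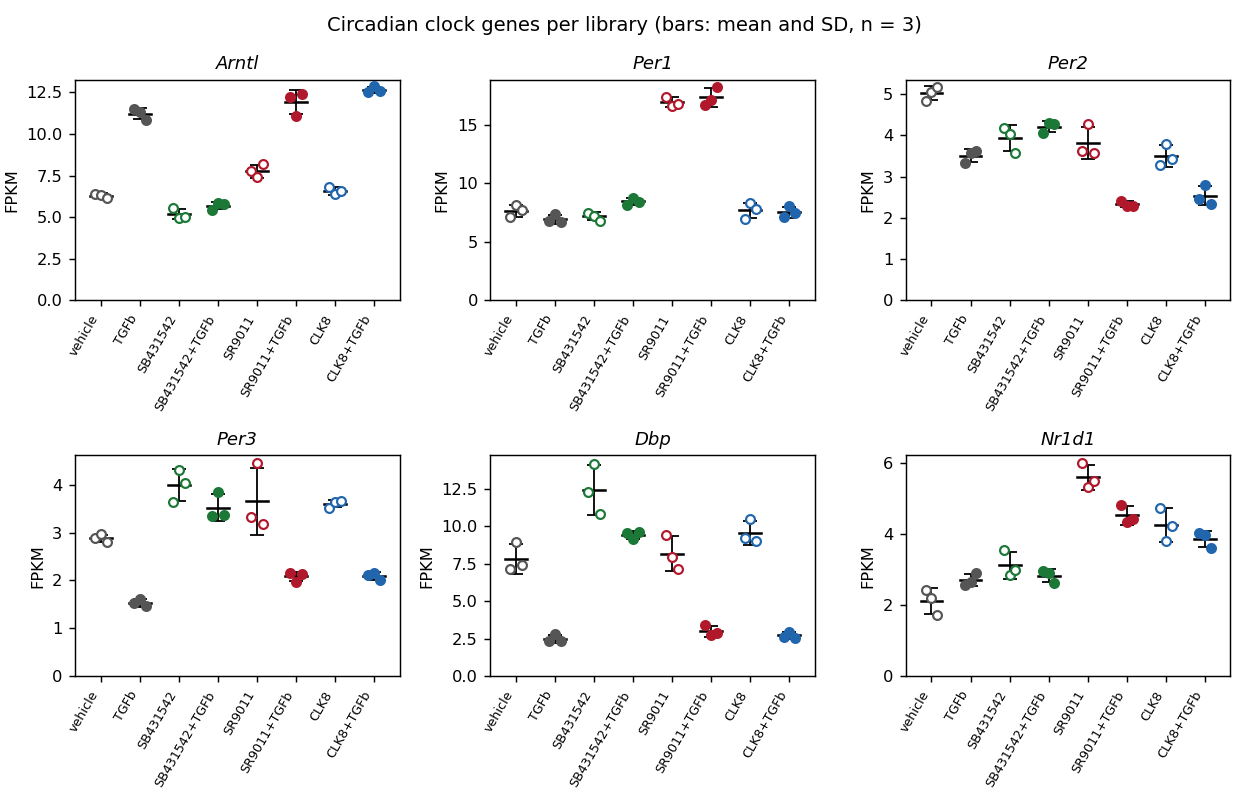
Points are FPKM (y axis) of single libraries in each group (x axis) for Arntl, Per1, Per2, Per3, Dbp and Nr1d1, and bars are the mean and SD of 3 libraries. Per1 stood at 16.9 FPKM with SR9011 and 17.4 with SR9011 and TGFb, against 7.65 in vehicle and 6.94 with TGFb.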

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

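The results in this part stand out because the effect of TGFb differed between cells with and without a compound, by an interaction test. Of the tests below, the splits with additive effects removed were chosen after the result was seen. With SB431542 the effect of TGFb differed for 3880 genes, 2433 higher and 1447 lower (TPM 1829 and 1732, quantile normalization 2032 and 1962). The largest negative interactions were in Ctsw (-5.01, SE 0.107, limma adjusted p = 6.41e-20), Postn (-3.85), Mfap4 (-3.37), Crispld2 (-3.33) and Nt5e (-3.19), all genes that TGFb alone raised. Mmp3 (3.07), Id2 (2.87), Aqp1 (2.81), Serpind1 (2.2) and the RAS family gene Rasl11a (2.08) had the largest positive ones, as TGFb lowered them less with the inhibitor (Mmp3 -0.61, Aqp1 -0.71) or was not called. Rasl11a stood at 258 ± 4.77 FPKM in vehicle, 58.4 ± 4.21 with TGFb and 238 ± 6.19 with SB431542 and TGFb (SD, n = 3). Of the 358 genes that TGFb changed at least 2-fold, 355 (99.2%) had a called interaction that opposed the TGFb effect. The genes were chosen by the effect that the interaction subtracts, so such counts lean towards opposing calls, here and below. Of 26 lists, 8 were called, led by the TGFb-SMAD response (17 of 22 genes lower and 2 higher, camera adjusted p = 2.36e-09, 0.00034 with an estimated correlation) and BMP-SMAD genes (8 of 8 higher, camera adjusted p = 5.35e-09, 0.0345 with an estimated correlation). Adjusted over the list alone, 18 TGFb-SMAD genes were lower and the BMP-SMAD count was the same.

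With SR9011 the effect of TGFb differed for 3607 genes, 1875 higher and 1732 lower (TPM 1614 and 1705, quantile normalization 1763 and 1961). Angptl7 had the largest positive interaction (3.15, SE 0.278, limma adjusted p = 1.01e-07), from 0.183 ± 0.025 FPKM with SR9011 to 8.8 ± 3.67 with SR9011 and TGFb (SD, n = 3). Next came Mgp (2.45), an inhibitor of calcification, the serine protease gene Htra3 (2.12), the troponin gene Tnnt2 (2.05) and Nrep (1.89). Mgp rose from 21 ± 3.61 to 154 ± 57.5 FPKM with SR9011 present, against 39.2 ± 4.21 and 48.7 ± 1.6 FPKM without it. The largest negative interactions were in Cdsn (-1.87), the stress pseudokinase gene Trib3 (-1.75), Fgf21 (-1.73), Lhfpl2 (-1.66) and the IL-33 receptor gene Il1rl1 (-1.65), which stood at 4.3 ± 0.375 FPKM with TGFb and 0.273 ± 0.081 with SR9011 and TGFb. Among the 358 genes, 237 (66.2%) had a called interaction opposing the TGFb effect and 35 one in its direction. Of 26 lists, 8 were called by camera, and 0 with an estimated correlation. Among the 8 were ER chaperones (11 of 17 higher and 1 lower, with Calr at 0.92, camera adjusted p = 4.56e-06, 0.149 with an estimated correlation) and proliferation genes (17 of 31 higher and 1 lower, with Bub1b at 0.38, camera adjusted p = 1.85e-05, 0.149 with an estimated correlation). So were other matrix proteins (14 of 25 higher and 3 lower, with Thbs1 at 1.60, camera adjusted p = 0.00052, 0.356 with an estimated correlation). Counts for these, adjusted over the list alone, were the same except for proliferation (19 higher, 1 lower). The call for p53 targets (7 of 16 lower and 2 higher, camera adjusted p = 0.0381, 0.356 with an estimated correlation) was lost after quantile normalization.

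With CLK8 the effect of TGFb differed for 900 genes, 517 higher and 383 lower (TPM 547 and 207). Angptl7 again had the largest positive interaction (2.32, SE 0.278, limma adjusted p = 1.66e-05), followed by the homeobox gene Dlx2 (1.39), Igfbp7 (1.35), the BMP signalling inhibitor Smad6 (1.23) and Fxyd3 (1.21). Fxyd3 was listed at 0 in all 3 libraries with CLK8 and TGFb and at 3.21 ± 1.32 FPKM in vehicle, 0.277 ± 0.24 with TGFb and 0.39 ± 0.079 with CLK8, so the floor limits its fall. Dlx2 rose from 4.97 ± 0.144 to 17.9 ± 0.733 FPKM with CLK8 present (SD, n = 3), against 9.06 ± 0.727 and 11.1 ± 0.344 FPKM without it. Il33 (-1.31), the imprinted gene Peg10 (-1.28), Aox3 (-1.22), Slpi (-1.18) and Ctsw (-1.16) had the largest negative ones, and Ctsw reached 17.4 ± 1.47 FPKM with CLK8 and TGFb, against 37.3 ± 0.515 with TGFb alone. Among the 358 genes, 73 (20.4%) had a called interaction opposing the TGFb effect and 44 one in its direction. The choice of these genes favours opposing calls, and no baseline for these counts was simulated. Of 26 lists, 15 were called and 6 with an estimated correlation. The 6 include the TGFb-SMAD response (9 of 22 higher and 1 lower, with Smad7, which CLK8 alone lowered, at 1.18, camera adjusted p = 3.05e-06, 0.00655 with an estimated correlation) and contractile genes (10 of 19 higher, with Myl9 at 1.08, camera adjusted p = 3.61e-09, 0.0184 with an estimated correlation). Immediate early genes (7 of 13 higher, with Fos at 1.08, camera adjusted p = 5.07e-09, 0.0184 with an estimated correlation) and BMP-SMAD genes (6 of 8 higher, camera adjusted p = 3.61e-09, 0.0184 with an estimated correlation) are among them too. The others are crosslinking and turnover genes (8 of 29 higher, camera adjusted p = 3.17e-07, 0.0131 with an estimated correlation) and AhR targets (2 of 6 higher, camera adjusted p = 0.000809, 0.0184 with an estimated correlation). For the same lists, counts adjusted over the list alone were the same except for TGFb-SMAD response (12 higher, 3 lower), matrix crosslinking and turnover (13 higher, 1 lower), contractile and myofibroblast (11 higher, 0 lower), BMP-SMAD response (7 higher, 0 lower), immediate early (10 higher, 0 lower) and AhR targets (3 higher, 0 lower). The call for ER chaperones (1 of 17 lower, camera adjusted p = 0.0479, 0.463 with an estimated correlation) was lost after TPM and after quantile normalization.

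Cholesterol synthesis genes were lower than additive where CLK8 and TGFb were combined, with a median interaction of -0.44, 18 of 23 genes lower (21 adjusted over the list alone) and camera adjusted p = 1.97e-17, 0.0518 with an estimated correlation. Mvd (-0.52), Fdps (-0.53) and Msmo1 (-0.73), all targets of SREBP2, were among them. The median nearest 0 was -0.418 after rescaling or quantile normalization, -0.399 when single libraries were left out and -0.427 after trends with transcript length and GC content were removed. These medians argue against scaling, one library or gene length and GC content as the whole cause. The count of genes called lower depended on the scaling, with 13 of 23 after TPM and 18 after quantile normalization. A combined effect of CLK8 and TGFb on sterol regulation could explain the lower levels as a hypothesis. An effect of the RNA kit stays open, and so does a longer time with CLK8 in the group with TGFb. The estimated correlation between genes leaves the list short of the threshold.

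Integrated stress response genes rose with SR9011 alone and less so under TGFb, with a median interaction of -0.86, 20 of 23 genes lower (the same adjusted over the list alone) and camera adjusted p = 1.26e-12, 0.149 with an estimated correlation. Trib3, for example, rose by 2.30 with SR9011 and had an interaction of -1.75, with Aldh1l2 at -0.92 and Slc3a2 at -0.87. The median nearest 0 was -0.884 after rescaling or quantile normalization, -0.812 when single libraries were left out and -0.842 after trends with transcript length and GC content were removed, which argues against scaling, one library or gene length and GC content as the whole cause. TGFb alone raised 16 and lowered 1 of these 23 genes, whereas with SR9011 present it lowered 10 and raised 2 (Trib3 -0.57). The list was not called there (camera adjusted p = 0.251, 0.823 with an estimated correlation). In that comparison 3498 of all genes fell and 1616 rose, so this split does not decide on a shared ceiling. A joint effect of SR9011 and TGFb on this response could explain this as a hypothesis that was not tested. The RNA kit stays open, and so does a longer time with SR9011 in the group with TGFb.

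Other splits of the libraries were counted for each comparison. Each pair of groups has only 10 splits, of which 1 (the real one) gave as many genes in all 10 comparisons, and this is too few to judge chance. The real counts and highest other splits were 6199 and 0 for TGFb against vehicle, 1910 and 0 for SB431542, 7801 and 18 for SR9011, 4959 and 1 for CLK8. They were 6740 and 0, 6871 and 0, and 4638 and 0 for SB431542, SR9011 and CLK8 under TGFb. For TGFb within SB431542, SR9011 and CLK8 they were 493 and 0, 5114 and 1, and 5865 and 1. Within SB431542, 4 of the 10 splits, the real one among them, part all 3 pairs of samples with the same number and the other 6 part 1 pair. For the interactions, 15 of 100 splits gave as many genes as the real 3880 with SB431542 (highest other 6367), 12 of 100 as the real 3607 with SR9011 (8351) and 13 of 100 as the real 900 with CLK8 (6245). The highest of these call several times the real count for CLK8, which points to a structure of the samples, namely the compound and TGFb effects that a mixed split carries into its groups, so these splits do not exclude chance. With those additive effects removed, 1 of 100 splits, the real one, gave as many genes for each compound, with highest other counts of 2517 for SB431542, 2114 for SR9011 and 1 for CLK8. This is the smallest share that 100 splits can give, and the interaction itself stayed in the data that were split. It argues against chance as the whole cause but does not exclude it.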

How the results depend on the processing

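Leaving out SR9011 replicate 1 from the gene list tests was chosen after the data were seen, and it gave 21 lists for SR9011 against vehicle (19 with it), 11 for TGFb within SR9011 (11) and 10 for the interaction (8). Of 23755 alternative tests of named genes, 21749 kept their call, 1443 stayed uncalled, 518 lost the call, 45 gained it and 0 were called in the opposite direction. Among single libraries, SR9011 replicate 1 was the only one left out of list tests, so dependence of list calls on the others was not tested. Of 3796 alternative list tests, 1695 kept the call, 1776 stayed uncalled, 180 lost it (129 of them with an estimated correlation) and 142 gained it. In the other 3, lists not called by camera were called by fry in the direction opposite to camera's, and the cause was not tested. These were TGFb-SMAD (camera adjusted p = 0.841, fry 0.0166) and matrix crosslinking (0.746, 0.0022) genes with CLK8 and TGFb against TGFb and the core clock with TGFb within CLK8 (0.895, 0.00225). Called lists numbered 167 of 338 tests and 38 with an estimated correlation. Without single libraries, called genes ranged over 5418 to 5856 for TGFb, 1337 to 1742 for SB431542, 7342 to 7863 for SR9011 and 4217 to 4558 for CLK8 against vehicle. They ranged over 6048 to 6453, 6299 to 6445 and 3957 to 4068 for these compounds under TGFb. For TGFb within the compounds they ranged over 199 to 513 (199 without SB431542 replicate 3, 244 and 243 without SB431542+TGFb replicates 1 and 2), 4325 to 5368 and 5222 to 5421, and for the interactions over 3253 to 4058, 2961 to 4111 and 615 to 868. The retained slope ranged over 0.119 to 0.151 with SB431542, 0.699 to 0.739 with SR9011 (0.702 with a pseudocount of 0.5 and 0.749 with FPKM of at least 5, against 0.717) and 0.922 to 0.955 with CLK8 (0.963 with FPKM of at least 5, against 0.943). Genes shared by SR9011 and CLK8 ranged over 2748 to 3646. The correlation of compound effects without and with TGFb ranged over 0.535 to 0.627 for SB431542 (0.6 with no filter and 0.636 with FPKM of at least 5, against 0.611), 0.802 to 0.823 for SR9011 and 0.71 to 0.755 for CLK8, and the cause of these shifts was not tested. With the replicate number as a block, 6265, 2030, 7860 and 5059 genes were called for TGFb, SB431542, SR9011 and CLK8 against vehicle and 547 for TGFb within SB431542 (493 without it). The block fits shifts by number that all 8 groups share. It is therefore not a pairing of the SB431542 groups alone, which was not fitted. For TGFb within SB431542, the block lost the calls of NRF2 targets (camera adjusted p = 0.061) and Pmaip1 (limma adjusted p = 0.0569) and changed no other call of a named gene or list. For the other groups compared, the residuals do not settle whether a number marks shared conditions. All 84 pairs with the same number had residual correlations of -0.324 to 0.415 (median 0.038, 32 over 0.1 and 35 under 0). Vehicle with SB431542 had 0.299, 0.317 and -0.007, while vehicle with SR9011 had -0.177, -0.065 and -0.184. Of 24 libraries, 13 correlated best with their own number. The 1 added to FPKM compresses the changes of genes near the floor, and an effect of depth on them was not tested.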

Other observations

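Of the tests in this part, the one on shared vehicle libraries was chosen after the result was seen. Gpnmb, the gene of a glycoprotein of lysosomes and melanosomes, was the gene that all 3 compounds raised among their largest rises, with and without TGFb. It stood at 5.25 ± 0.606 FPKM in vehicle, 13.2 ± 1.23 with SB431542, 47.3 ± 7.11 with SR9011 and 33.1 ± 2.33 with CLK8 (SD, n = 3), and under TGFb at 0.757 ± 0.055, 9.95 ± 1.13, 18.7 ± 0.78 and 7.63 ± 1.46 FPKM. TGFb alone lowered it (log2 -1.83, limma adjusted p = 2.26e-12). TGFb lowered 11 of 18 autophagy and lysosome genes and raised 2 (the same adjusted over the list alone), without a call for the list (camera adjusted p = 0.0683, 0.403 with an estimated correlation).

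The cells expressed part of the list of portal fibroblast and mesothelial markers. In vehicle, Upk3b stood at 252 ± 9.81 FPKM, Cd34 at 222 ± 5.89, Gpm6a at 174 ± 1.79, Upk1b at 68.3 ± 2.76, Wt1 at 27.3 ± 0.41 and Msln at 5.65 ± 0.869 (SD, n = 3). Of the 8 portal fibroblast and mesothelial markers tested, 6 fell and 2 rose with TGFb, without a call for the list (camera adjusted p = 0.286, 0.568 with an estimated correlation). With SR9011 7 fell and 1 rose (camera adjusted p = 0.00231, 0.153 with an estimated correlation), and with CLK8 5 fell and 2 rose (camera adjusted p = 0.00253, 0.145 with an estimated correlation), each the same adjusted over the list alone. Upk3b was among those that fell with TGFb (-1.51), SR9011 (-2.24) and CLK8 (-2.10), while Msln rose with all 3 (0.39, 1.42 and 0.76). Of 11 listed portal fibroblast and mesothelial markers 3 (Thy1, Entpd2 and Clec3b) stayed under 1 FPKM in every library. In vehicle Mfap4 stood at 0.56 FPKM and Gas6 at 68.07. Of 21 measured quiescent stellate cell genes 8 stayed under 1 FPKM in every library, while Dcn reached 1626.03 FPKM. Markers of other liver cells were mostly near the floor, with 6 of 7 measured hepatocyte genes (highest Apoa2, 1.86 FPKM), 3 of 4 macrophage genes (Cd68, 2.9), 8 of 9 liver endothelial genes (Tek, 2.92) and 4 of 7 cholangiocyte genes (Krt7, 7.27) under 1 FPKM in every library. Krt7 stood at 6.65 FPKM in vehicle, 1.14 with SR9011 and 1.95 with CLK8. Krt19 stood at 2.14, 0.65 and 0.79 in these groups, and Sox9 at 0.53, 2.46 and 1.87.

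SR9011 and CLK8 changed 3245 genes in the same direction against vehicle, 2220 up and 1025 down, with 655 in opposite directions, where independent lists would share 1395 up and 434 down. Both raised Gpnmb (2.94 and 2.45) and Nr1d1 (1.08 and 0.75), and both lowered Ccl2 (-3.58 and -1.96) and Angptl7 (-4.36 and -3.44). The correlation was 0.532, and 0.399 and 0.509 between comparisons that share no library. Shared vehicle libraries gave 0.499 in simulations of unchanged groups, which holds only where no gene changes and is no baseline here. The covariance was 0.083 against 0.00291 simulated, and 0.054 and 0.063 between comparisons that share no library. These covariances argue against shared vehicle libraries as the whole cause. The correlation without a shared library was 0.392 after quantile normalization at its smallest, which argues against scaling between libraries. A common response of these cells to both compounds could explain the overlap as a hypothesis, and an effect of the solvent or the RNA kit was not tested.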
